A study of Schizosaccharomyces pombe with 23 samples.

How the data were processed

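Chromatin immunoprecipitation of fission yeast was hybridised to Agilent arrays of 60-mer probes in 2 colours, with ChIP DNA in the red (Cy5) and whole-cell extract in the green (Cy3) channel on each array per the labels. The targets were H3K9me2 (9 comparisons), Pir1 with a MYC or GFP tag (6 comparisons) and FLAG-tagged Rec12 in meiosis (1 comparison). Per the labels, cells were fixed in 3% paraformaldehyde, with dimethyl adipimidate as well for the tagged Pir1 strains, and Rec12 samples were not fixed. Culture times for nitrogen starvation of the H3K9me2 sample and for reduced glucose, and the meaning of SD and SA, are not given in the sources used here.

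Per the file headers, the authors extracted the images with Agilent Feature Extraction, version 11.5.1.1 on 3 arrays, 12.0.3.1 on 18 and 9.5.1.1 on 1. The deposited scanner files hold the raw signal intensity of each channel and, per the file headers, a processed signal intensity that is background-subtracted and linearly dye-normalised within the array. The deposited value table is the ratio of processed red to processed green, and its log2 equals the log2 ratio recomputed from the scanner files to within 6.21e-09. The log2 ratio used here is therefore log2 of the authors' processed ChIP over processed whole-cell extract signal. No normalisation between arrays is stated in the file headers, and the genome build of the probe design is not given in the sources used here. The arrays came from 13 slides, and 7 comparisons had both arrays on 1 slide. Slide differed along with strain for H3K9me2 in the pir1 deletion, in the ddb1 deletion and with GFP-Pir1-SA. It also differed in every Pir1-MYC comparison and for GFP-Pir1-SD and GFP-Pir1-SA binding. For nitrogen the slides are not known.

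Each array held 41551 probes that were not controls. Their sequences were matched exactly to the ASM294v3 reference: 41449 (99.8%) had at least 1 match, 40396 exactly 1, 1053 more than 1 and 102 none. The silent mating-type region was read from 36 probes that the array names mat and that had no exact match. The span of mat probes with exactly 1 match, II 2109775-2138777, served only to mark domains there. Pericentromeric repeats were the longest stretch of each chromosome without a protein-coding gene (I 3751730-3790923, II 1596745-1648231, III 1064444-1142615), with 362 probes, against 58 in the mitochondrial genome. Log2 ratios were centred on the array median of all probes, with no loess or quantile step. Probes with outlier flags (2 to 7274 per array) were then left out. Medians were 968 to 1264 for the extract and 923 to 1304 for the ChIP signal, 58.8 to 492 and 30.1 to 139 times background. At most 36 probes per array were dim in the extract channel and at most 2 were saturated, so few were limited by extract signal. Dim probes were not counted in the ChIP channel. No scanner file of the nitrogen-starved array was used here, and that comparison used the authors' value table for both arrays. Flagged probes were kept there, although the nitrogen-replete array was the one with 7274.

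A gene's value was the mean over probes overlapping its body with 250 bp each side, measured on both arrays, over 12606 annotated genes (5113 protein-coding). Lists written from prior knowledge used genes with at least 2 probes: 9 meiotic island genes, 13 other Mmi1 targets, 3 phosphate genes, 13 mating and early meiosis genes, 9 glycolytic genes, 84 genes within 50 kb of chromosome ends, 131 ribosomal protein genes, 160 tRNA genes, 68 snRNA and snoRNA genes and 13 Tf2 elements, besides the 3 probe regions and 6 genes that mark the strains' genotypes. Each list median of differences was given with a bootstrap SD over genes (2000 draws) and its percentile among 10000 random lists. In these each member was replaced by 1 of the 50 protein-coding genes nearest in mean level over both arrays. This percentile describes the list and is not a test across arrays. Genes named in the text are the island genes, members of other lists with the largest or smallest difference of their list, and, by rule, the 5 largest gains and 5 largest drops with at least 3 probes and a level of at least 1 on either array, 1 per 5 kb locus. Others are said to be named after their values were seen.

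Domains were called where ratios smoothed over 500 bp reached 1 on the log2 scale over at least 3 probes, joined within 1 kb. H3K9me2 islands were called on both replete wild-type arrays outside the comparison, and domains near ends, at pericentromeres or the silent region, or of at least 10 kb were set apart as permanent. Pir1 sites were called on the wild-type array of the other tag, with no untagged control among the samples, and Rec12 hotspots on the mean of both arrays. Shares seen (mean at least 1) carry 95% Wilson intervals. Rec12 was also compared over 1 kb windows.

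Each of 23 samples was its own group with 1 array, so no test across arrays was possible, and the differences between the 3 replete wild-type H3K9me2 arrays served as the spread for that mark. Comparisons, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were centring on the mode, normexp background correction (offset 50, limma), loess within arrays (limma), the authors' value table, leaving out dim or saturated probes, gene body alone or with 500 bp each side, the median over probes, scaling to the pericentromeric repeats, other wild-type controls, calling thresholds of 1.5 and 0.6, domains of at least 5 probes, and for Rec12 division by the array SD. Normexp used median signals, since the files used here held no mean signals. The ChIP channel alone and probes with exactly 1 match were added after the data were seen.

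The steps were tested on simulated data in which 200 genes were shifted against noise of SD 0.3. For H3K9me2 in tor2ts, true differences of -2, -1, -0.5, 0.5, 1 and 2 came back as -1.97, -0.96, -0.45, 0.54, 1.04 and 2.03. Of 1000 unshifted lists of 9 genes, 6.1% fell outside the central 95% of random lists, 100% of lists lowered by 1 fell at or below its lower end, and 60 of 60 inserted domains were found with 0 elsewhere. These lists were drawn at random from protein-coding genes of any level, not at the level of the island genes. For GFP-Pir1 in tor2ts the values were -1.98, -1.01, -0.43, 0.53, 0.97 and 2.01, with 5.2%, 100% and 58 of 58. The other comparisons were not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.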

Results

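The series title names a nuclear RNA processing network that the TOR kinase targets to support proliferation and control developmental genes. Chromatin immunoprecipitation was read on tiling microarrays of fission yeast for 3 targets. These were histone H3 dimethylated at lysine 9 (H3K9me2, a mark of heterochromatin), the nuclear RNA-elimination factor Pir1 carrying a MYC or a GFP tag, and Rec12, the enzyme that breaks DNA in meiosis. Pir1, called Iss10 in the reference annotation, works with the YTH-domain protein Mmi1 in destroying meiotic transcripts in growing cells. There were 23 samples in 23 groups of 1 array each, forming 16 comparisons: 9 for H3K9me2, 6 for Pir1 and 1 for Rec12. The strains were wild type, tor2ts (a temperature-sensitive allele of the TORC1 kinase gene tor2), deletions of pir1, ubi4, ddb1 and cul4, and forms of GFP-Pir1 that the labels call SD and SA without saying what the letters stand for. Per the labels, most cultures grew in rich medium at 30 °C, and the glucose, nitrogen and meiosis samples are described with their comparisons. The median whole-cell extract signal per array was 968 to 1264 and the median ChIP signal 923 to 1304. These medians were 58.8 to 492 times the local background in the extract channel and 30.1 to 139 times in the ChIP channel, over the 22 arrays with a scanner file. With 1 array per group there was no replicate check, so no difference below carries a p-value, and the number of arrays limits precision. All values are log2(ChIP/whole-cell extract) with the array median at 0, and each difference is the test array minus its reference, so a drop or a gain is a lower or higher value on 1 test array, without a test.

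The extract channel lacked DNA at each deleted gene. Extract signal, here and below, is the log2 signal after the array median was set to 0, relative to the median of the same probes over all arrays. It was -7.91 over pir1 in the pir1 deletion, -9.11 over ddb1 in the ddb1 deletion and -5.37 over cul4 in the cul4 deletion. Over ubi4 it was -4.24 in the H3K9me2 ubi4 deletion array and -2.93 in the Pir1-MYC one. The tor2 allele cannot be checked this way, since tor2 lay between -0.45 and 0.22 on all 22 arrays.

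The main list, fixed before the arrays were read, held 9 genes in or beside facultative heterochromatin islands, patches of H3K9me2 outside the permanent heterochromatin. They were mei4 (SPBC32H8.11, chromosome II 1473068-1475285), a forkhead transcription factor of middle meiosis, ssm4 (SPAC27D7.13C, I 4534674-4536736), a dynactin-like protein of meiotic nuclear movement, and mcp7 (SPAC13A11.03, I 578450-579948), a meiotic recombination protein. The others were mcp5 (SPBC216.02, named num1 in the reference, II 898056-901363), a meiotic cortical anchor, mug8 (SPAC32A11.01, I 2445242-2447714) and mug9 (SPCC70.09C, III 2369108-2369852), both induced in meiosis, mbx2 (SPBC317.01, II 3626639-3628658), a MADS-box transcription factor, vps29 (SPAC15E1.06, I 3727368-3728410), a retromer subunit, and the island gene SPAC8C9.04 (I 3646220-3648784).

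In the plain wild type, H3K9me2 was highest within the list at mei4 (4.83), then ssm4 (3.82), mcp7 (3.47), vps29 (3.14) and SPAC8C9.04 (2.63). Lower levels were found at mcp5 (1.86), mug9 (1.71), mbx2 (1.43) and mug8 (0.58). The 3 wild-type arrays grown in replete medium gave list medians of 2.63 (plain), 1.62 (2% glucose) and 2.54 (nitrogen-replete). Their largest difference, 1.02, is the only spread between comparable arrays here. Single genes differed by 2.54 at mei4, 2.40 at mcp7, 1.61 at SPAC8C9.04, 1.55 at mbx2, 1.42 at mug9 and 1.29 at ssm4. The differences at mug8 (0.96), mcp5 (0.65) and vps29 (0.19) were smaller. A gene's H3K9me2 difference below these values is no larger than that between replete wild types. Permanent heterochromatin differed too, the chromosome ends by the most: the pericentromeric repeats lay at 5.99, 7.77 and 7.91, the silent mating-type region at 6.13, 8.36 and 8.39, and the genes within 50 kb of chromosome ends at 3.26, 6.82 and 6.86.

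The first comparison asked whether H3K9me2 at developmental genes depends on TOR. In tor2ts, all 9 island genes had less H3K9me2 than in the plain wild type, though mug8 was not lower (0.03) against the 2% glucose one: ssm4 (-2.93), mei4 (-2.80), mcp7 (-2.73), SPAC8C9.04 (-1.90), mbx2 (-1.80), mcp5 (-1.29), mug9 (-1.28), vps29 (-1.07) and mug8 (-0.89). Non-coding RNAs overlapping ssm4 (SPNCRNA.4051, -3.02), mcp7 (SPNCRNA.2243, -2.92) and mei4 (SPNCRNA.5202, -2.88) led the genes with the largest drop, followed by SPNCRNA.3669 (-2.17), which overlaps the permease gene per1, and SPCC576.19C (-1.94). The phosphate genes, which the same RNA-elimination system controls, were lower by a median of -0.82, with the acid phosphatase gene pho1 at -0.84 and the transporter gene tgp1 at -0.36. Their median level was -0.04 in the wild type and -0.85 in tor2ts, so as a list they were enriched on neither array. Permanent heterochromatin hardly differed from the plain wild type: -0.05 at the pericentromeric repeats, -0.20 at the silent mating-type region and -0.15 at the chromosome ends, each turning positive under a within-array loess fit. Against the 2% glucose wild type, however, all 3 were lower (5.74 against 7.77, 5.96 against 8.36 and 3.26 against 6.82), so whether they differ rests on the control. The island list median was 0.73 against 2.63, a difference of -1.80 (bootstrap SD over genes 0.49). It fell at percentile 0.00 of 10000 random lists of genes with similar mean level on both arrays, whose central 95% spanned -0.36 to 0.10. For H3K9me2 these lists can draw on chromosome-end genes, which reach such levels too (median 3.26 in the plain wild type). Here and below, the percentile therefore does not set the island genes against the genome at large.

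Outside the island genes in tor2ts, other Mmi1 targets (0.17), mating and early meiosis genes (0.01), glycolytic genes (0.02) and tRNA genes (0.06) were close to the wild type. The ribosomal protein genes (0.24, 116 of 130 higher), snRNA and snoRNA genes (0.25) and Tf2 elements (0.15) were slightly higher, but the ribosomal protein genes turned to -0.01 and the Tf2 elements to -0.40 against the 2% glucose wild type. The ribosomal RNA genes SPRRNA.50 (1.98), SPRRNA.42 (1.75) and SPRRNA.45 (1.74) stood highest by difference, but against the 2% glucose wild type they were at -1.66, -1.83 and -1.78, so their direction rests on the choice of control. The mitochondrial genome was at -1.54, and at 0.96 under a within-array loess fit. Of 69 islands called on the other wild-type arrays, 34 (49.3%, 95% interval 37.8 to 60.8) were seen in the wild type and 16 (23.2%, 14.8 to 34.4) in tor2ts. Of 20 permanent domains, 17 and 16 were seen. The -0.88 of the island list against the 2% glucose wild type is smaller than the largest difference between replete wild types.

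Deleting pir1 asked whether the islands need Pir1. H3K9me2 was near or below the array median at every island gene but vps29, from -0.57 at mug8 to 0.29 at SPAC8C9.04. At vps29 it stayed at 2.27. Among the others mei4 stood at -0.26, ssm4 at -0.01 and mcp7 at -0.46, differences of -5.09, -3.82 and -3.93. SPAC8C9.04 (-2.34), mbx2 (-1.87), mcp5 (-1.66), mug9 (-1.62), mug8 (-1.14) and vps29 (-0.88) were lower as well. The non-coding RNAs SPNCRNA.5202 at mei4 (-5.17), SPNCRNA.2243 at mcp7 (-4.30) and SPNCRNA.4051 at ssm4 (-4.12) had the largest drops genome-wide. Genes near the chromosome ends went the other way, with 83 of 84 higher than in the plain wild type (4.86 against 3.26, median 1.11), among them SPNCRNA.4522 (2.91), SPBPB2B2.15 (2.75) and SPAC977.05C (2.66). Against the 2% glucose wild type, however, the chromosome-end genes were at -0.74, the silent mating-type region turned from 0.36 to -1.88 and the pericentromeric repeats from 0.57 to -1.07. The non-coding genes SPNCRNA.7207 (1.85) and prl104 (1.78) were higher too, but negative against the nitrogen-replete wild type.

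The island median in the pir1 deletion was -0.01 against 2.63, a difference of -1.87 (bootstrap SD 0.77, percentile 0.00, random lists 0.06 to 0.72), and -1.04 against the 2% glucose wild type. Other Mmi1 targets (-0.10), phosphate genes (-0.07), mating and early meiosis genes (-0.01), ribosomal protein genes (-0.07) and snRNA and snoRNA genes (-0.03) were near the wild type, and the glycolytic genes were at -0.19. The tRNA genes (0.23), Tf2 elements (0.43) and mitochondrial genome (0.39) were higher, but turned negative with loess, and the tRNA genes (-0.23) and Tf2 elements (-0.11) also against the 2% glucose wild type. Of the called islands, 45 of 69 (65.2%, 53.4 to 75.4) were seen, against 34 in the wild type, and 61 of 69 were higher than in the plain wild type, the only control used for this count. At a calling threshold of 1.5 both arrays showed 32 of 43.

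The next pair asked whether ubiquitin-pathway genes limit H3K9me2 when TOR is impaired. Deleting the polyubiquitin gene ubi4 in tor2ts went with more H3K9me2 at all 9 island genes: mcp7 (2.44), ssm4 (2.43), mei4 (2.30), mbx2 (1.46), mug9 (1.41), mcp5 (1.27), mug8 (1.04), vps29 (0.95) and SPAC8C9.04 (0.33). The gains at mei4, mbx2, mug9 and SPAC8C9.04 were smaller than the largest difference between replete wild types at the same gene. The phosphate genes were higher by a median of 0.86, with the transporter gene pho84 at 0.94 and tgp1 at 0.12, but their median level only reached -0.03, from -0.85. By contrast ura4, a uracil synthesis gene often used as a marker, had 0.59 against 5.54 in tor2ts (-4.96), and at 0.59 it stood apart from 4.84 to 8.61 on the other H3K9me2 arrays. As ura4 can be a strain marker, this drop is not read as an effect of deleting ubi4. SPNCRNA.6639 (-2.06), SPNCRNA.4512 (-2.05), SPNCRNA.2014 (-2.02) and SPNCRNA.7143 (-1.13) were the next lowest. By gain, prl104 (4.76), the Golgi transporter gene gdt1 (3.70) and SPBPB21E7.09 (3.66) were highest ahead of SPNCRNA.2243 at mcp7 (2.56) and SPNCRNA.4051 at ssm4 (2.49). Of these, prl104 and gdt1 lie within 50 kb of an end of chromosome I. Over the island list the median was 1.84 against 0.73, a difference of 1.41 (bootstrap SD 0.38, percentile 100, random lists -0.39 to 0.05).

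Elsewhere in the ubi4 deletion, pericentromeric repeats (0.44) and the silent mating-type region (0.76) were a little higher, the mitochondrial genome was at 1.64 and tRNA genes at 0.20. Chromosome-end genes had a median difference of 0.14, but their median level was lower, 2.995 against 3.26 in tor2ts. Other Mmi1 targets (-0.12), mating and early meiosis genes (-0.04), glycolytic genes (0.09), ribosomal protein genes (-0.05), snRNA and snoRNA genes (0.00) and Tf2 elements (0.09) were near tor2ts. Of the 69 called islands, 29 (42.0%, 31.1 to 53.8) were seen, against 16 in tor2ts, but with normexp background correction the order turned, to 26 of 55 against 30.

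Deleting ddb1, which encodes the adaptor of the Cul4 ubiquitin ligase, in tor2ts also went with more H3K9me2 at all 9 island genes. The gains were 2.33 at mbx2, 2.07 at mei4, 2.02 at mcp5, 2.00 at ssm4, 1.77 at mcp7, 1.096 at vps29, 0.82 at mug9, 0.64 at SPAC8C9.04 and 0.32 at mug8. Those at mei4, mcp7, mug9, SPAC8C9.04 and mug8 were smaller than the largest difference between replete wild types at the same gene. Larger gains appeared at non-coding loci away from the list, led by SPNCRNA.394 (6.10 against 0.80, chromosome II 2198477-2199461, with extract at -1.66), SPNCRNA.5587 (3.71), SPNCRNA.831 at the secretion gene avl9 (3.56), SPNCRNA.5382 (3.32) and SPNCRNA.5211 at ivn1 (3.18). Genes near the ends differed both ways, from SPAC750.01 (-3.78) to SPCC569.01C (2.99). By rank SPNCRNA.4500 (-3.81), SPAC977.14C (-3.12), SPBC1348.05 (-3.08), SPBPB2B2.16C (-2.99) and SPAC977.04 (-2.91) were lowest. Of the end genes 55 of 84 were lower (median -0.82), and the median turned to 0.19 with probes that match the genome once. For the island list the median was 2.501 against 0.74, a difference of 1.77 (bootstrap SD 0.47, percentile 100, random lists -0.44 to 0.28). At 20 loci H3K9me2 was higher by at least 2 and at 5 it was lower by as much. At 3 of the lower loci, those of SPBC1348.05, SPBPB2B2.16C and SPAC977.04, 95 to 100% of the probes of these genes match elsewhere too, so the signal cannot be assigned to a single site. One of the gains, at the amine oxidase gene cao1, lies in DNA almost absent from this strain's extract.

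The remaining lists in the ddb1 deletion differed little: other Mmi1 targets 0.10, phosphate genes -0.02, mating and early meiosis genes 0.06, glycolytic genes -0.12, ribosomal protein genes -0.02, tRNA genes 0.02, snRNA and snoRNA genes -0.04, Tf2 elements 0.14, pericentromeric repeats 0.26 and silent mating-type region 0.44. The mitochondrial genome was at 0.98. With loess the repeats, the silent region, the Tf2 elements and the mitochondrial genome turned negative. Only 14 of 69 called islands (20.3%, 12.5 to 31.2) were seen, against 16 in tor2ts. The counts were 14 of 55 against 30 with normexp and 18 of 43 against 20 at a threshold of 1.5. The order turned to 17 of 135 against 14 at a threshold of 0.6 and 15 of 45 against 14 with domains of at least 5 probes. Of the 69 islands 54 were lower.

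Growth in less glucose asked whether the sugar supply sets H3K9me2 at these genes. At 0.5% glucose against 2%, all 9 island genes were lower, mei4 (-1.20), mcp7 (-1.06), mcp5 (-0.75), vps29 (-0.69), mug9 (-0.59), ssm4 (-0.44), SPAC8C9.04 (-0.29), mbx2 (-0.25) and mug8 (-0.19). SPNCRNA.5202 at mei4 (-1.21), SPCC70.08C (-0.97) and SPNCRNA.566 at mcp5 (-0.85) were among the largest drops. By gain SPNCRNA.1180 at the meiotic cohesin gene rec11 (0.78), SPNCRNA.6610 (0.66), nam3 (0.64), SPNCRNA.137 (0.63) and SPAC1039.03 (0.60) came highest. Chromosome-end genes were at 0.20 with 72 of 83 higher, pericentromeric repeats at 0.08 and the silent mating-type region at 0.12, and all 3 turned negative under a loess fit (-0.12, -0.19 and -0.24). As a list, the island genes had a median of 0.73 against 1.62, a difference of -0.59 (bootstrap SD 0.18, percentile 0.00, random lists 0.01 to 0.23), smaller than the 1.02 between replete wild types. Other Mmi1 targets (-0.01), phosphate (0.10), mating and early meiosis (-0.02), glycolytic (0.08), ribosomal protein (0.02), tRNA (-0.08), and snRNA and snoRNA genes (-0.01), Tf2 elements (0.06) and the mitochondrial genome (0.16) hardly differed, the last 2 turning negative with loess. Called islands were seen in 43 of 48, against 45 at 2%, and in 56 of 73 against 54 at a threshold of 0.6.

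At 0.1% glucose H3K9me2 was lower over most of the heterochromatin. Among the island genes mei4 (-3.64), ssm4 (-3.14) and vps29 (-3.09) were lowest, then mcp5 (-1.89), mcp7 (-1.87), mug9 (-1.16), SPAC8C9.04 (-1.14), mbx2 (-0.76) and mug8 (-0.61). SPNCRNA.4051 at ssm4 (-3.81), SPNCRNA.5202 at mei4 (-3.65), SPNCRNA.391 (-3.13) and SPNCRNA.389 (-2.92) had the largest drops. The pericentromeric repeats (5.80 against 7.82, -2.25), the silent mating-type region (5.83 against 8.36, -2.44) and the chromosome-end genes (-1.28, 78 of 83 lower) were lower too, and the telomeric helicase gene tlh1 was at -1.95. The end genes turned to 0.30 when both arrays were scaled to their pericentromeric repeats. The largest gains by the naming rule were SPNCRNA.3136 at avl9 (1.75), SPNCRNA.5587 (1.25), SPNCRNA.4653 at mug89 (1.01), the chromatin-remodelling gene iec1 (0.89) and nam3 (0.17), the last within its standard error over probes (0.205).

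Glycolytic genes at 0.1% glucose were lower in 9 of 9 (median -0.78, with the aldolase gene fba1 at -1.67), as were the meiosis regulator mei2 (-1.37) among the mating and early meiosis genes (median -0.27), pho84 (-1.03) among the phosphate genes (-0.95) and the tRNA genes (-0.79). As lists, however, they had little enrichment to lose. The glycolytic genes had a median level of -0.65 against -0.08 at 2% glucose, and the highest list median at 2% was 0.35, for the phosphate genes. Ribosomal protein genes went both ways (0.10, rps402 -1.67, rps1001 1.03), and other Mmi1 targets (-0.08), snRNA and snoRNA genes (0.00), Tf2 elements (-0.07) and the mitochondrial genome (0.06) were near 2% glucose, although a loess fit turned the Tf2 elements to 1.71. As a list, the island genes had a median of -0.11 against 1.62, a difference of -1.87 (bootstrap SD 0.66, percentile 0.00, random lists -1.19 to -0.15). Of the called islands 19 of 48 (39.6%, 27.0 to 53.7) and 17 of 22 permanent domains were seen. Shrinking all enrichment by the share lost at the pericentromeric repeats would alone give -0.99.

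Nitrogen starvation, a signal for mating and meiosis, asked the same question for another nutrient. All 9 island genes had less H3K9me2 after starvation: mei4 (-4.75), mcp7 (-3.64), ssm4 (-2.75), mug9 (-2.50), mcp5 (-1.92), mbx2 (-1.52), SPAC8C9.04 (-1.46), mug8 (-0.80) and vps29 (-0.43). SPNCRNA.5202 at mei4 (-4.94), SPNCRNA.2243 at mcp7 (-3.87), SPNCRNA.4051 at ssm4 (-2.86) and SPNCRNA.566 at mcp5 (-2.16) led the drops. Permanent heterochromatin was higher instead, at the chromosome ends (0.55, 73 of 84), the pericentromeric repeats (0.38) and the silent mating-type region (0.39). The tRNA genes were higher too (0.37, 137 of 160). The transfer RNA gene SPBTRNAGLU.06 (2.62), SPNCRNA.2019 (2.58), SPNCRNA.283 (2.47) and SPNCRNA.280 (2.46) had the largest gains.

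The island median after nitrogen starvation was 0.38 against 2.54, a difference of -1.92 (bootstrap SD 0.59, percentile 0.00, random lists 0.29 to 1.27), and -1.08 with the 2% glucose wild type as control, where mug8 (0.16) and mbx2 (0.03) were no longer lower. Tf2 elements (0.24), snRNA and snoRNA genes (0.15) and glycolytic genes (0.13, 9 of 9) were slightly higher, and other Mmi1 targets (-0.07), phosphate genes (0.05), mating and early meiosis genes (-0.05) and ribosomal protein genes (0.01) differed little. Of the called islands 48 of 57 were seen against 37, and 49 of 57 were higher, but at a calling threshold of 1.5 the order turned, to 32 of 35 against 34. The authors' value table served both arrays, since no scanner file of the starved sample was used here, and the labels do not give the length of starvation.

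**Figure D1:**
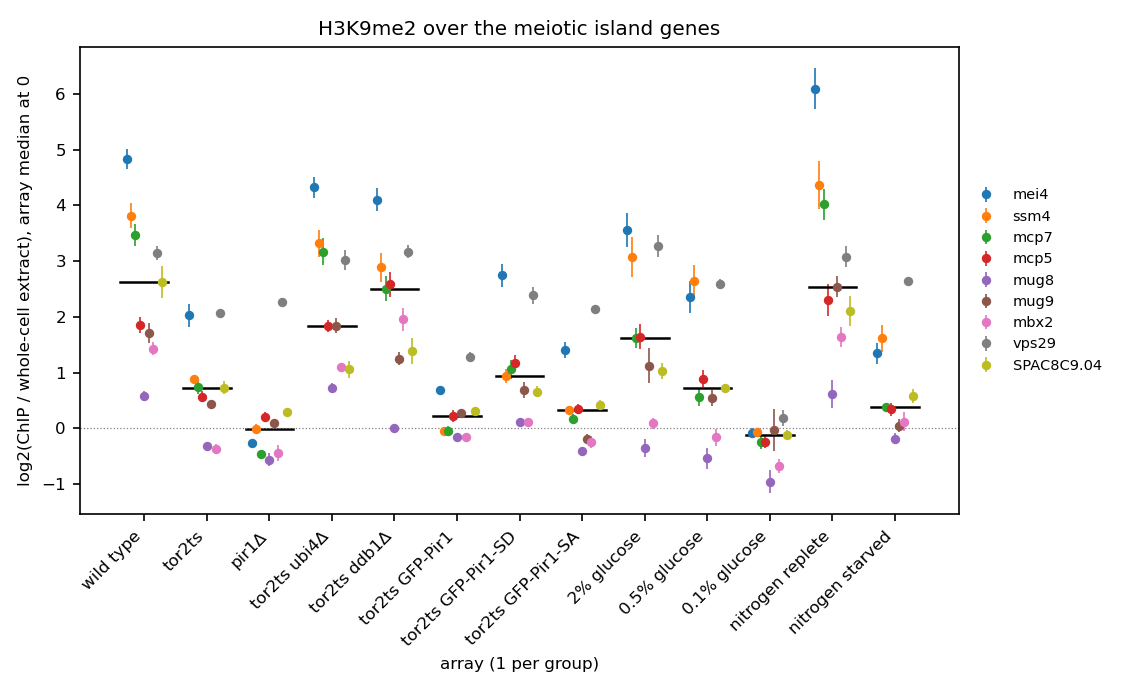
H3K9me2 as log2(ChIP/whole-cell extract), array median at 0, on the y axis for each H3K9me2 array on the x axis (1 array per group); points are the 9 island genes with the standard error over probes, and the black line is their median. The medians go from 2.63 in the plain wild type to 0.73 in tor2ts and -0.01 in the pir1 deletion, and from 0.73 in tor2ts to 1.84 with ubi4 deleted.

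Altered forms of Pir1 in tor2ts asked whether Pir1 itself carries the effect on H3K9me2. With GFP-Pir1-SD in place of GFP-Pir1, H3K9me2 was higher at all 9 island genes, most at mei4 (2.05), mcp7 (1.25), vps29 (1.0998), mcp5 (0.96) and ssm4 (0.93), and less at mug9 (0.41), SPAC8C9.04 (0.36), mug8 (0.27) and mbx2 (0.27). SPNCRNA.5201 at mei4 (2.28), SPNCRNA.2243 at mcp7 (1.31), SPNCRNA.4051 at ssm4 (1.23), SPNCRNA.5604 (1.15) and the ribosomal RNA gene SPRRNA.43 (1.15) had the largest gains. The end genes SPNCRNA.4522 (-1.34), SPBPB2B2.15 (-1.30), SPAC977.05C (-1.30) and SPAC750.02C (-0.86), and SPNCRNA.5505 (-0.37), had the largest drops. For the list as a whole the median was 0.88 against 0.22, a difference of 0.93 (bootstrap SD 0.30, percentile 100, random lists -0.14 to 0.11), still under the 1.02 between replete wild types and short of the 2.63 of the plain wild type. Pericentromeric repeats (0.34), tRNA genes (0.23), the mitochondrial genome (0.24) and the silent mating-type region (0.18) were somewhat higher. Ribosomal protein genes (-0.11) and snRNA and snoRNA genes (-0.15) were lower, and other Mmi1 targets (0.04), phosphate (-0.09), mating and early meiosis (0.01), glycolytic (-0.06) and chromosome-end genes (0.01) and Tf2 elements (0.09) close to 0. Scaling to the pericentromeric repeats put the silent mating-type region at -0.23 and a loess fit put the Tf2 elements at -0.28.

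With GFP-Pir1-SA the island genes split: vps29 (0.85), mei4 (0.72), ssm4 (0.37), mcp7 (0.26), mcp5 (0.20) and SPAC8C9.04 (0.13, -0.00 with loess) were higher, and mug9 (-0.45), mug8 (-0.24) and mbx2 (-0.10) lower. Chromosome-end genes carried the large differences, with SPAC750.01 (4.55), SPAC186.08C (4.53), SPAC977.14C (3.64), SPAC186.06 (3.34) and SPAC186.02C (2.46) on top and 78 of 84 higher (4.95 against 1.71, median 0.66). SPNCRNA.4755 at the eisosome gene fhn1 (-1.06), SPNCRNA.1496 at rpb8 (-0.80), SPNCRNA.2122 (-0.76) and SPNCRNA.6667 (-0.74) were lowest, the last turning to 0.04 in the ChIP channel alone. The list median was 0.31 against 0.14, a difference of 0.20 (bootstrap SD 0.17, percentile 95.3, random lists -0.13 to 0.24), inside the range of random lists. Pericentromeric repeats (0.65), silent mating-type region (0.63), mitochondrial genome (0.68), Tf2 elements (0.38) and tRNA genes (0.23) were higher. The snRNA and snoRNA genes (-0.37), glycolytic genes (-0.35), ribosomal protein genes (-0.28) and phosphate genes (-0.14) were lower, and other Mmi1 targets (-0.02) and mating and early meiosis genes (0.08) near 0. Of those that were higher, a loess fit turned the Tf2 elements and the mitochondrial genome (-0.22) negative and the tRNA genes to -0.00, and normexp put the silent region at -0.00. Called islands were seen in 7 of 69 with GFP-Pir1, 13 with SD and 47 (68.1%, 56.4 to 77.9) with SA, where 63 of 69 were higher. Extract signal over pir1 on these arrays was -0.86 with GFP-Pir1, -0.20 with SD and -1.27 with SA. This signal thus differed from GFP-Pir1 by 0.67 with SD and by -0.41 with SA. However, arrays of strains with pir1 but without GFP-Pir1 already ranged from -0.45 to 0.41. The SA form also read 0.67 on its Pir1 array. Whether the strains of these H3K9me2 arrays differed in pir1 DNA, besides the form of Pir1, is therefore not settled.

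Binding of Pir1-MYC in tor2ts asked whether TOR keeps Pir1 on chromatin. All 9 island genes had less Pir1-MYC than in the wild type, led by mei4 (0.86 against 1.88, -1.01), mcp7 (-0.85), mbx2 (-0.56), SPAC8C9.04 (-0.56), mug8 (-0.48), ssm4 (-0.45) and mug9 (-0.45), with mcp5 (-0.24) and vps29 (-0.22) last. The largest drops were at SPNCRNA.6511, inside stb3, a homologue of a Sin3-binding protein gene (0.43 against 2.07, -1.64, chromosome II 4252785-4254421), the phosphate-responsive RNA nc-tgp1 (-1.36), the small nucleolar RNA gene snR46 (-1.28), the ribosomal protein gene rps2202 (-1.16) and SPNCRNA.2944 (-1.13). Ribosomal protein genes (-0.51, 131 of 131 lower), snRNA and snoRNA genes (-0.40, 67 of 68), tRNA genes (-0.33, 150 of 160), phosphate genes (-0.67), glycolytic genes (-0.29, 9 of 9) and other Mmi1 targets (-0.12, rec10 at -0.63) were lower as well. Mating and early meiosis genes were at -0.02. Ribosomal RNA (SPRRNA.50, 2.37), the mitochondrial genome (2.40), chromosome-end genes (0.58, 80 of 84) and Tf2 elements (0.15) were higher, but the Tf2 elements turned to -0.03 with loess. The median difference over probes was 0.06 at the silent mating-type region and 0.48 at the pericentromeric repeats. Their median levels were nevertheless lower in tor2ts (0.49 against 0.55 and 0.53 against 0.68), and the repeats turned to -0.06 with probes that match once. The list median was 0.42 against 0.80, a difference of -0.48 (bootstrap SD 0.09), at percentile 15.4 of random lists (-0.57 to -0.10), so the island genes did not stand out from other bound genes. Of 79 sites called with the GFP tag, 43 (54.4%, 43.5 to 65.0) were seen in the wild type and 1 (1.27%, 0.224 to 6.83) in tor2ts. On the tor2ts array, which all 3 Pir1-MYC comparisons use, extract signal over cao1 and cbm1 was -1.60 (33.1% of the typical signal) while the ChIP channel stood at 0.10, so whether both DNAs came from the same culture is not settled. This array was also on a different slide from the other Pir1-MYC arrays. In these comparisons strain therefore cannot be told apart from slide or from this array.

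Deleting ubi4 or cul4, which encodes the ligase scaffold, in tor2ts asked whether protein turnover limits Pir1 on chromatin. Both deletions were set against the same tor2ts array, which was on another slide, so their differences cannot be told apart from that array or slide. Without ubi4, Pir1-MYC was higher at all 9 island genes: mei4 (0.82), mcp7 (0.81), mug8 (0.59), mcp5 (0.54), mbx2 (0.42), mug9 (0.40), SPAC8C9.04 (0.31), ssm4 (0.20) and vps29 (0.11). The phosphate genes were higher by a median of 0.68 (pho1 0.74, tgp1 0.52), with nc-pho1 at 1.04, and SPNCRNA.3866 at the oxygenase gene isp7 (1.43) and SPNCRNA.2243 at mcp7 (1.04) were among the largest gains. The marker gene ura4 (1.89, standard error over probes 0.76) and the deleted ubi4 itself (1.07) also appeared, the latter at -0.63 in the ChIP channel alone, where the extract DNA is missing. Ribosomal RNA (SPRRNA.50, -1.87), the mitochondrial genome (-1.63), and chromosome-end genes (-0.36, 82 of 84) were lower. The island median was 0.96 against 0.42, a difference of 0.42 (bootstrap SD 0.12, percentile 99.6, random lists -0.06 to 0.34), and 22 of 79 sites (27.8%, 19.2 to 38.6) were seen. Other Mmi1 targets (0.15), mating and early meiosis genes (0.17) and tRNA genes (0.33) were higher, and glycolytic (0.06), ribosomal protein (-0.02), and snRNA and snoRNA genes (0.01) and the silent region (-0.03) near 0. Tf2 elements (-0.22) and pericentromeric repeats (-0.21) were lower, but at 0.12 and 0.09 in the ChIP channel alone, with the repeats at 0.14 on probes that match once. The median level of the repeats was higher, 0.77 against 0.53 in tor2ts.

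Without cul4, the gains at the island genes were mei4 0.64, mcp7 0.48, SPAC8C9.04 0.41, mug9 0.38, vps29 0.38, mcp5 0.37, mbx2 0.23, ssm4 0.08 and mug8 0.03 (-0.03 with the median over probes). SPNCRNA.6511 in stb3 was higher by 0.97 and SPNCRNA.5201 at mei4 by 0.86, behind prl6 (1.18, standard error 0.77) and ahead of the transfer RNA gene SPBTRNAILE.06 (0.79). Ribosomal RNA (SPRRNA.42, -2.33, SPRRNA.45, -2.30, SPRRNA.48, -2.19), the mitochondrial genome (-2.24), chromosome ends (-0.47), silent mating-type region (-0.41), pericentromeric repeats (-0.36) and Tf2 elements (-0.24) were lower. The island median was 0.73 against 0.42, a difference of 0.38 (bootstrap SD 0.07, percentile 99.7, random lists -0.02 to 0.30), or 0.60 with normexp background correction. Phosphate genes (0.34), tRNA genes (0.22) and other Mmi1 targets (0.13) were higher, and mating and early meiosis (0.05), glycolytic (0.03), ribosomal protein (0.07), and snRNA and snoRNA genes (0.05) near 0. Of the 79 sites 8 (10.1%, 5.22 to 18.7) were seen against 1 in tor2ts, but at a calling threshold of 0.6 the order turned, to 4 of 343 against 12.

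The GFP tag put the same question of TOR and Pir1 binding to a separate strain pair. GFP-Pir1 was lower in tor2ts at all 9 island genes: mcp7 (1.03 against 3.04, -2.01), mug9 (-2.01), mei4 (1.74 against 3.47, -1.73), SPAC8C9.04 (-1.67), mug8 (-1.63), ssm4 (-1.56), mcp5 (-0.81), vps29 (-0.60) and mbx2 (-0.41). SPNCRNA.2243 at mcp7 (-2.42), SPNCRNA.3101 at mug8 (-2.08), SPNCRNA.5201 at mei4 (-2.02) and SPNCRNA.4051 at ssm4 (-1.97) had the largest drops. Other Mmi1 targets were lower too (-0.72, 11 of 13), from mug45 at -1.90 to the meiotic RNA gene sme2 at 0.23. One locus on chromosome II went sharply the other way, SPNCRNA.577 (3.41 against 0.44, 2.97, 4255755-4259164, with extract at -0.93), followed by SPNCRNA.4035 (2.06), the kinetochore gene dad5 (1.37), SPNCRNA.6668 (1.17) and SPNCRNA.6675 (1.12). The island median was 0.93 against 2.60, a difference of -1.63 (bootstrap SD 0.32, percentile 0.00, random lists -1.07 to -0.07), and -0.99 in the ChIP channel alone.

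More widely in GFP-Pir1, snRNA and snoRNA genes (-0.46, snR46 at -1.90) and ribosomal protein genes (-0.40, 130 of 131, rps2202 at -1.80) were lower. Glycolytic genes (-0.25), phosphate genes (-0.28), tRNA genes (-0.22) and the silent mating-type region (-0.06) were lower in the main setting but turned to 0.09 and 0.15 in the ChIP channel alone for the first pair, to 0.04 over gene bodies for tRNA genes and to 0.01 with loess for the silent region. Chromosome-end genes (0.33, 74 of 84), the mitochondrial genome (2.37), pericentromeric repeats (0.09) and Tf2 elements (0.05) were higher by median difference, though the median level of the repeats was 0.48 against 0.51. Mating and early meiosis genes stood at 0.05, with mei2 at 0.58 and rep1, a regulator of premeiotic replication, at -1.25. All 70 sites called with the MYC tag were lower, and 13 (18.6%, 11.2 to 29.2) were seen against 49 (70.0%, 58.5 to 79.5) in the wild type. Extract signal over pir1 was 0.99 in the wild type and -0.03 in tor2ts, a difference of -1.02. The wild type was thus the array above the typical level, and the strains differed in pir1 DNA as well as in tor2.

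The altered forms asked whether changes in Pir1 bring it back to chromatin when TOR is impaired. GFP-Pir1-SD was higher than GFP-Pir1 in tor2ts at all 9 island genes, foremost mbx2 (5.05 against 2.30, 2.74, with extract at -1.73), then mei4 (1.32), mcp5 (0.89), mug8 (0.86), mcp7 (0.68), mug9 (0.44), ssm4 (0.43), vps29 (0.27) and SPAC8C9.04 (0.18). The phosphate genes followed (1.21, pho1 1.31, pho84 0.79), with nc-tgp1 (1.64) and nc-pho1 (1.39) beside SPNCRNA.577 (1.54) and SPNCRNA.7373 at cbl1 (1.48) among the largest gains, while no gene met the rule for a drop. Other Mmi1 targets (0.23, mug1 0.74), glycolytic genes (0.18), the silent region (0.29) and mating and early meiosis genes (0.10, rep1 0.92) were higher. Ribosomal protein genes (0.01) and chromosome ends (-0.10) were near 0, and the mitochondrial genome was at -1.96. The Tf2 elements (0.25) and pericentromeric repeats (0.22) turned to -0.05 and -0.01 with loess, and the tRNA genes (0.14) and snRNA and snoRNA genes (0.10) to -0.01 and -0.01 in the ChIP channel alone. The island median was 1.71 against 0.93, a difference of 0.68 (bootstrap SD 0.24, percentile 97.7, random lists 0.25 to 0.67), barely outside the random lists. Of the 70 sites 32 (45.7%, 34.6 to 57.3) were seen against 13, and at a threshold of 1.5 both arrays showed 10 of 11.

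GFP-Pir1-SA differed little from GFP-Pir1: mcp5 (0.23), mei4 (0.09) and mug8 (0.00) were at or above it, mei4 and mug8 both turning to -0.08 with normexp. Below it were mug9 (-0.40), SPAC8C9.04 (-0.23), mbx2 (-0.22), mcp7 (-0.16), ssm4 (-0.10) and vps29 (-0.08), with mbx2 at 0.02 and vps29 at 0.07 in the ChIP channel alone. The largest drops were at mamRNA (SPNCRNA.1715.2, a long non-coding RNA bound by Mmi1, -0.92), SPNCRNA.577 (-0.88), dad5 (-0.67), SPNCRNA.5333 (-0.66) and SPNCRNA.1197 (-0.59, turning to 0.06 in the ChIP channel alone). The largest gains were SPNCRNA.4673 (0.87), SPNCRNA.5920 at rep1 (0.78), SPNCRNA.566 at mcp5 (0.29), SPNCRNA.5201 at mei4 (0.21) and SPNCRNA.5256 (0.09, turning to -0.04 with normexp and -0.05 with loess). The island median was 0.87 against 0.93, a difference of -0.10 (bootstrap SD 0.07, percentile 45.7, random lists -0.22 to 0.00), or -0.20 with normexp, and 8 of 70 sites (11.4%, 5.91 to 21.0) were seen. Other Mmi1 targets (-0.01), phosphate (-0.13), mating and early meiosis (0.01), glycolytic (-0.09), chromosome-end (-0.01), ribosomal protein (-0.09), tRNA (-0.12), and snRNA and snoRNA genes (-0.02), Tf2 elements (-0.00), pericentromeric repeats (0.01) and the silent region (0.09) differed little. The mitochondrial genome (-0.21) turned to 0.36 in the ChIP channel alone, and extract signal over pir1 was higher by 0.70 with SA.

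**Figure D2:**
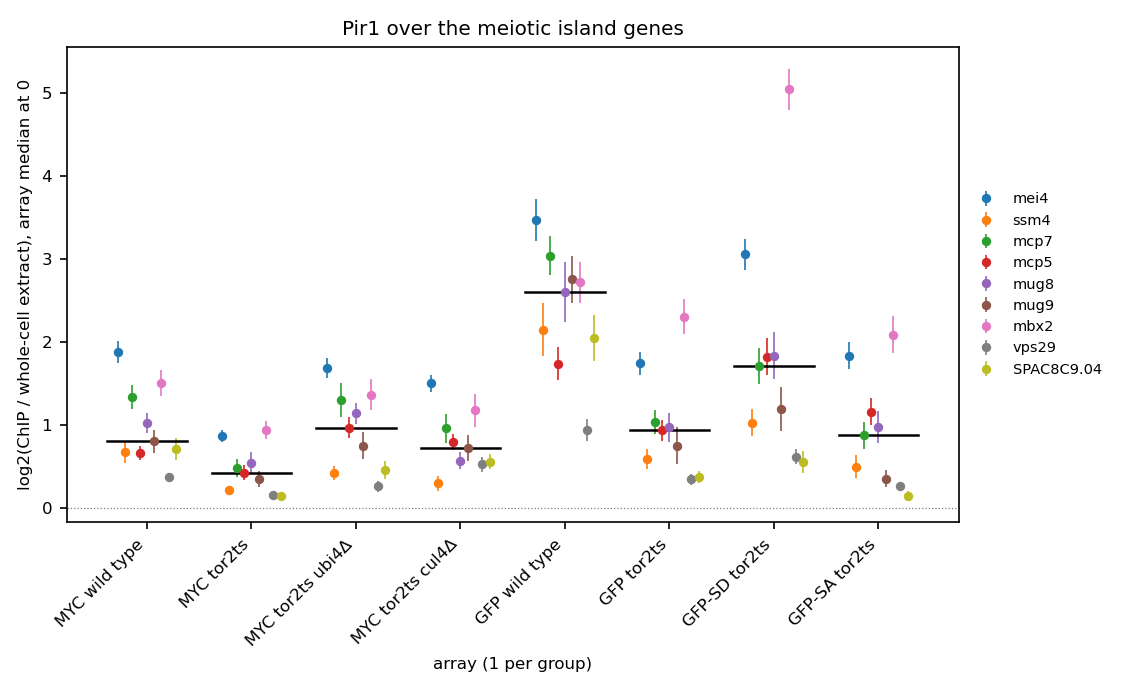
Pir1 as log2(ChIP/whole-cell extract), array median at 0, on the y axis for each Pir1 array on the x axis (1 array per group); points are the 9 island genes with the standard error over probes, and the black line is their median. The median goes from 0.80 to 0.42 in tor2ts with the MYC tag and from 2.60 to 0.93 with the GFP tag, and stands at 1.71 with SD and 0.87 with SA.

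**Figure D3:**
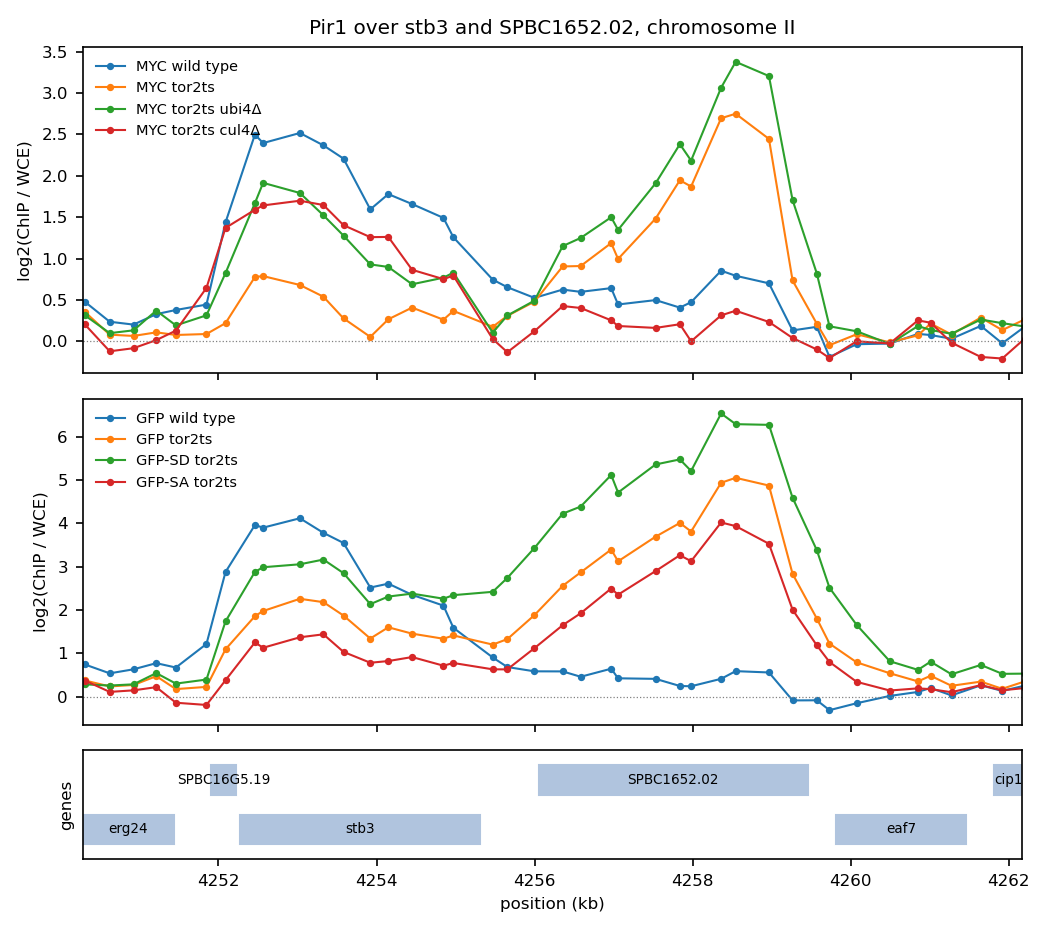
Pir1 log2(ChIP/whole-cell extract) of each probe on the y axis against position on chromosome II in kb on the x axis, with the MYC arrays on top, the GFP arrays in the middle and genes at the bottom. SPNCRNA.6511 in stb3 goes from 3.26 in the GFP wild type to 1.81 in tor2ts, while SPNCRNA.577 to its right goes from 0.44 to 3.41.

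Rec12 binding in synchronous meiosis asked whether the SD form of Pir1 alters where or how much meiotic DNA breakage machinery binds. The cells carried pat1-114 and rad50S, which start meiosis on warming and keep Rec12 attached to its breaks. Per the labels they were starved of nitrogen at 26 °C for 6 h and then kept at 34 °C for 4.5 h. Rec12 was lower with GFP-Pir1-SD than with GFP-Pir1 at 145 of 151 hotspots. The largest difference was at the peroxiredoxin gene pmp20 and SPCC330.07C (-1.64, chromosome III 118720-120710), and the metal transporter gene fet4 (II 328039-334056), named after its values were seen, was at -1.39. SPNCRNA.2450 at ssd2 (-1.98), SPNCRNA.2957 (-1.86), SPNCRNA.4667 (-1.78), SPNCRNA.1111 (-1.70) and SPNCRNA.3026 (-1.51) had the largest drops among genes. Of 6 hotspots that were higher, the largest (1.35, 2.54 against 1.19, I 2932079-2933611) and one at 0.15 (I 2936032-2939059) lie at cao1 and cbm1, in DNA nearly absent from both extracts. SPNCRNA.3328 (0.69, standard error 0.72, -0.29 in the ChIP channel alone) lies in the same deleted stretch, ahead of SPNCRNA.328 (0.53), SPNCRNA.2162 (0.43), the ribosomal protein gene rps27 (0.41) and SPNCRNA.6663 (0.22).

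The Rec12 hotspot median was 1.08 with SD against 1.68, and the median of the differences was -0.68, or -0.38 with a calling threshold of 0.6. The Pearson correlation between both arrays was 0.805 across 1 kb windows (12571, which are not independent replicates), with 99 against 149 hotspots at 1 or more. Ranked by the mean of both arrays, the strongest hotspots kept a share of 0.413 of their linear enrichment, the middle ones 0.511 and the weakest 0.467. Ranked by the SD array these shares were 0.474, 0.524 and 0.381, and by the GFP-Pir1 array 0.401, 0.427 and 0.622. Glycolytic genes (-0.65, 9 of 9, the decarboxylase gene pdc101 at -0.90), phosphate genes (-0.61), chromosome ends (-0.23, 75 of 84), the silent region (-0.32) and the mating gene ste11 (-0.86, list -0.07) were lower. The island genes were at -0.12 with mbx2 (-0.76), SPAC8C9.04 (-0.60), mcp7 (-0.30), mug8 (-0.15, 0.01 in the ChIP channel alone), ssm4 (-0.12, 0.06 with the median over probes) and mug9 (-0.09) lower and vps29 (0.36) and mcp5 (0.23) higher. The remaining gene, mei4, stood at 0.01 and turned negative in several alternatives. Other Mmi1 targets (0.11), ribosomal protein (-0.01) and tRNA genes (0.05) were near 0, and the mitochondrial genome was at 0.41. The snRNA and snoRNA genes (-0.11), pericentromeric repeats (-0.12) and Tf2 elements (0.04) changed sign in at least 1 alternative, to 0.01, 0.03 and -0.05. Extract signal over pir1 was higher by 1.40 in the SD strain, so the strains differed in pir1 DNA as well as in the form of Pir1.

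**Figure D4:**
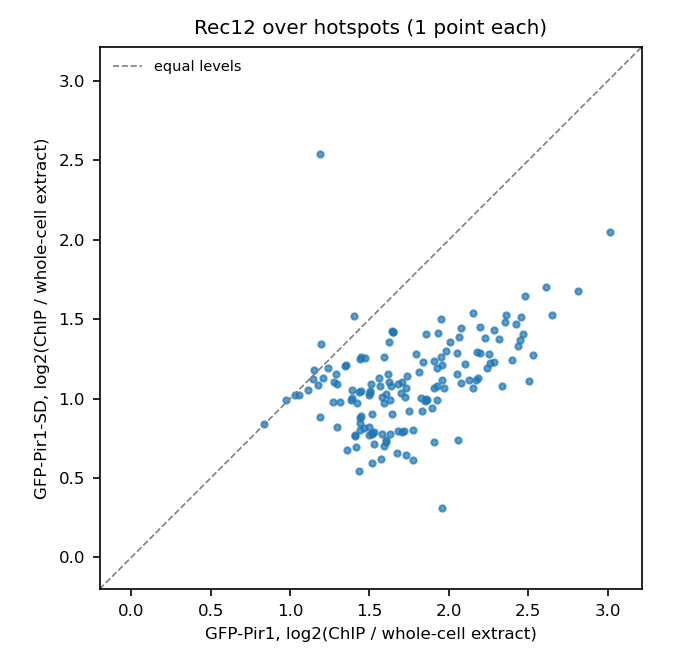
Rec12 log2(ChIP/whole-cell extract) at each of 151 hotspots, 1 point per hotspot, with GFP-Pir1 on the x axis, GFP-Pir1-SD on the y axis and equal values on the dashed line. Of these, 145 lie below the line and the point farthest above it, at 1.19 and 2.54, is the cao1 hotspot in deleted DNA.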

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

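All tests of explanations in this part were chosen only after the results they address had been seen.

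At 0.5% and 0.1% glucose 2 parts of the heterochromatin differed from 2% glucose in opposite directions. Genes within 50 kb of chromosome ends were at 0.20 at 0.5% glucose and at -1.28 at 0.1%, and the silent mating-type region at 0.12 and -2.44. Neither difference between the doses was tested, and the small values at 0.5% turned negative with loess (-0.12 and -0.24).

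Whole-cell extract, which the comparisons use only as a denominator, showed DNA missing over cao1 and cbm1 (chromosome I 2934381-2939335, 17 probes) in several strains. Extract signal, relative to the median of the same probes over all arrays, was -7.80 in the tor2ts ddb1 deletion, -4.28 in the Pir1-MYC wild type, -1.60 in Pir1-MYC tor2ts, and -8.52 and -9.35 in the Rec12 arrays with GFP-Pir1 and GFP-Pir1-SD. In Pir1-MYC tor2ts the ChIP channel read 0.10 over the same probes, so whether both DNAs of that array came from the same culture is not settled, and all 3 Pir1-MYC comparisons use it. Over pir1 itself (5 probes) the extract stood apart from the other arrays at 0.99 in the GFP-Pir1 wild type, -0.86 and -1.27 in the H3K9me2 tor2ts arrays with GFP-Pir1 and GFP-Pir1-SA, 0.67 in the Pir1 array of GFP-Pir1-SA and 1.51 in the Rec12 array of GFP-Pir1-SD. Mitochondrial DNA was enriched in 3 Pir1 arrays, at 0.47 in Pir1-MYC tor2ts, 0.45 in GFP-Pir1 tor2ts and 0.25 in GFP-Pir1-SA, where the other Pir1 arrays had -1.13 to -1.90.

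Pir1 was lower at the island genes in tor2ts with both tags. With GFP, the island difference fell at percentile 0.00 of random lists of the genes nearest in level. That does not decide on a general loss of ChIP enrichment. Only 242 genes reached 1 on either array, so the lists can include genes bound more weakly than the strongest island genes. The ChIP channel alone gave -0.99 against -1.63 for the ratio. This argues against the extract channel as the whole cause, though not as a part of it. With MYC, the extract channel is likewise argued against only as the whole cause (-0.35 in the ChIP channel alone against -0.48 for the ratio). A general loss stays open for MYC as well, where the percentile was 15.4. So does pir1 copy number, since the extract over pir1 differed by 0.070 but may not come from the cells of the ChIP. The MYC arrays of tor2ts and wild type were also on different slides, which cannot be told apart from the strain. With GFP the extract signal over pir1 was -0.03 in tor2ts and 0.99 in the wild type, a difference of -1.02. Fewer copies of tagged pir1 than in that wild type may thus explain part of the drop. The tor2 allele that the design names also stays open, untested.

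At 0.1% glucose H3K9me2 was lower at the island genes and in permanent heterochromatin. If immunoprecipitation had merely been less efficient, each gene would keep the share of enrichment left at the pericentromeric repeats, 0.244. The 9 island genes lay below that prediction by a median of -0.89 (SD 0.24), or -0.90 (SD 0.37) at the 7 with a level of at least 1 at 2% glucose, since mug8 and mbx2 had little to lose, and the list difference fell at percentile 0.00 of random lists. With the share left at the silent mating-type region, 0.171, the gap was -0.74 (SD 0.19, or 0.28 over those 7). These values do not decide on lower efficiency, since island genes and repeats did not scale together between replete wild types either. The plain wild type had 2.63 at the island genes and 5.99 at the repeats, the 2% glucose one 1.62 and 7.77. The median gaps are also smaller than the 1.02 between island medians of replete wild types. Nor does the percentile decide, since the random lists can draw on chromosome-end genes. Lower efficiency stays open, as does an effect of glucose itself, untested.

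Rec12 binding was lower at nearly all hotspots with GFP-Pir1-SD. A general loss takes the same share of enrichment everywhere: ranked by the mean of both arrays, the share left differed by -0.054 (SD 0.059) between the strongest and weakest hotspots and by -0.098 (SD 0.032) between the strongest and middle ones. It cannot be told apart from an uneven loss, since the ranking uses the levels behind the shares, and the contrasts became 0.093 (SD 0.030) and -0.050 (SD 0.040) ranked by the SD array, and -0.22 (SD 0.055) and -0.025 (SD 0.042) by the other. The SD extract also carried pir1 DNA higher by 1.40, so a higher copy number of the altered gene may contribute. The difference between the Pir1 forms that the design names was not separated from either.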

How the results depend on the processing

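The ChIP channel alone and probes with exactly 1 match were chosen after the data had been seen. No paired analysis was possible because each group had 1 array. The median signal over background was at least 30.1 on all 22 arrays with a scanner file, and dim probes were counted in the extract channel only. Not run: normexp on mean signals (medians were used), the scanner-based alternatives for nitrogen, and pericentromere scaling for Pir1 and Rec12.

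All 16 main differences kept their direction under all alternatives run, with 170 of 186 values within 1 spread of the main value: the SD of the 3 replete wild-type arrays (0.56) for H3K9me2, the bootstrap SD for Pir1 and Rec12. Ranges were -2.04 to -0.88 for H3K9me2 in tor2ts, -2.16 to -1.04 in the pir1 deletion, 1.19 to 1.43 with ubi4 deleted, 1.41 to 1.88 with ddb1 deleted, -0.62 to -0.42 at 0.5% and -2.04 to -1.47 at 0.1% glucose, -2.04 to -1.08 without nitrogen, 0.78 to 1.103 for SD and 0.15 to 0.24 for SA. For Pir1 they were -0.71 to -0.35 for MYC tor2ts, 0.33 to 0.53 with ubi4 and 0.31 to 0.60 with cul4 deleted, -1.92 to -0.99 for GFP tor2ts, 0.54 to 0.93 for SD and -0.20 to -0.04 for SA, and -0.92 to -0.38 for Rec12. Values farther away, cause not tested, were -0.88 (tor2ts), -1.04 (pir1 deletion) and -1.08 (nitrogen) with the 2% glucose control, each less than the largest replete wild-type difference (1.02) away from its main value; with normexp -0.71 (MYC tor2ts), 0.60 (cul4), 0.93 (SD), -0.20 (SA) and -0.82 (Rec12); in the ChIP channel alone -0.35 (MYC tor2ts), -0.99 (GFP tor2ts) and -0.48 (Rec12); and for Rec12 -0.79 with loess, -0.72 with 1-match probes, -0.83 divided by the SD, and -0.92 and -0.38 at thresholds of 1.5 and 0.6.

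Shares of sites seen (%) moved with the calling, since a stricter threshold calls stronger sites. In some alternatives the order of test and reference turned: ubi4 (47.3 against 54.5 in tor2ts) with normexp, nitrogen (91.4 against 97.1) at 1.5, and at 0.6 Pir1 cul4 (4 of 343 sites against 12 in tor2ts), 0.5% glucose (76.7 against 74.0 at 2%) and ddb1 (12.6 against 10.4 in tor2ts, also 33.3 against 31.1 with 5 probes). At 1.5: H3K9me2 tor2ts 46.5, ubi4 74.4, ddb1 41.9, SD 46.5, SA 88.4; Pir1 cul4 22.9, GFP tor2ts 90.9, SD 90.9, SA 81.8. At 0.6: tor2ts 10.4, pir1 31.3, ubi4 20, 0.5% glucose 76.7, 0.1% glucose 24.7, nitrogen 53.1, SD 11.2, SA 29.1; Pir1 ubi4 5.83, cul4 1.17, GFP tor2ts 3.13, SD 14.6, SA 2.34. With 5 probes: ubi4 55.6, ddb1 33.3, GFP tor2ts 35.3, SD 67.6. With normexp, cause not tested: tor2ts 54.5, pir1 80.0, SA 80.0; Pir1 cul4 30.0, GFP tor2ts 9.49, SD 28.5.

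Among 192 results for other lists 99 had the opposite sign in at least 1 alternative (180 of 2033 values), and among 291 for named genes 25 did (40 of 3328). The 25 values below (19 for lists, 6 for genes) turned a result that exceeded the largest difference between replete wild types (H3K9me2) or 2 standard errors or bootstrap SDs (Pir1 and Rec12), and the cause was not tested. With loess: H3K9me2 tor2ts mitochondrial 0.96, MYC tor2ts Tf2 -0.028, GFP tor2ts silent region 0.0075, SD Tf2 -0.046 and pericentromeric -0.011, SA SPNCRNA.5256 -0.054 (-0.044 with normexp). Gene body alone: GFP tor2ts tRNA 0.0435 (10 genes measured). Mode: Rec12 Tf2 -0.021. With 1-match probes pericentromeric: MYC tor2ts -0.061, MYC ubi4 0.14, Rec12 0.032. ChIP channel alone: MYC ubi4 Tf2 0.12, pericentromeric 0.0899, ubi4 gene -0.63; GFP tor2ts phosphate 0.15, glycolytic 0.092; SD tRNA -0.0133, snRNA -0.0134; SA mitochondrial 0.36, mbx2 0.023, SPNCRNA.1197 0.063; Rec12 snRNA 0.0079, Tf2 -0.0476, mug8 0.0064. No scaling moved the median of all genes by 0.1 or more.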

Other observations

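All hypotheses and tests in this part were chosen only after the data had been seen, and the genes named here outside the lists were chosen after their values were seen.

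While Pir1 was lower at the island genes in tor2ts, it was higher at a locus on chromosome II. SPBC1652.02 (II 4256050-4259457), which encodes an amino acid transporter and lies beside the Sin3-related gene stb3, had GFP-Pir1 at 0.33 in the wild type, 3.29 in tor2ts, 4.82 with SD and 2.45 with SA. With the MYC tag the same gene stood at 0.48 in the wild type, 1.33 in tor2ts, 1.76 with ubi4 deleted and 0.17 with cul4 deleted. A few kb away, SPNCRNA.6511 inside stb3 went the other way, from 3.26 to 1.81 with GFP and from 2.07 to 0.43 with MYC, then to 1.29 without ubi4 and 1.40 without cul4. Genes higher in tor2ts by at least 0.5, and at a level of at least 1 there, numbered 70 with MYC and 22 with GFP, 13 of them with both, and with probes that match the genome once 2 remained, SPNCRNA.577 and SPBC1652.02, which overlap each other. The methyltransferase gene omt3 went from -0.04 to 1.81 with GFP and from -0.25 to 0.05 with MYC.

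H3K9me2 at avl9, a gene of the secretory pathway, stood at 3.72 in the tor2ts ddb1 deletion and at 2.11 at 0.1% glucose, against 0.55 at 2% glucose, 0.90 in the plain wild type, 1.24 in the nitrogen-replete wild type and 0.78 in tor2ts. The gene leu1, a leucine synthesis gene used as an integration marker, had extract signal of 1.05 in the GFP-Pir1 wild type and 0.59 in GFP-Pir1 tor2ts. In the Pir1 arrays of SD and SA it was 0.54 and 0.31. The H3K9me2 arrays had 0.37 with GFP-Pir1, 0.49 with SD and 0.13 with SA. The Rec12 arrays had 1.46 with GFP-Pir1-SD and 0.03 with GFP-Pir1. Over pir1, the extract signal of the Pir1 arrays in tor2ts differed from GFP-Pir1 by 0.70 for SA and 0.04 for SD. In the H3K9me2 arrays it differed by -0.41 for SA and 0.67 for SD, so the 2 sets of arrays did not give the same order.

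At the loci with the highest ratios named here the extract channel itself stood below the median of the same probes over all arrays: SPBC1652.02 at -0.91 in GFP-Pir1 tor2ts and -1.53 with SD, SPNCRNA.577 at -0.93 and -1.68, mbx2 with SD at -1.73 and SPNCRNA.394 in the ddb1 deletion at -1.66. Loci picked for a high ratio tend to have a low denominator by that choice alone, so nothing is concluded from these values by themselves. On the GFP-Pir1-SD array, however, the low stretches found from the extract channel alone were at mbx2 (-2.08), SPBC1652.02 (-1.88) and cbl1 (-1.91). All of these lie at the largest gains named for that array. Choice by ratio does not account for them, so a low extract adds to the ratios there, and its cause was not tested. Such stretches were not particular to that array. The 2% glucose wild type had one near an end of chromosome I (5548099-5555918, -1.86). The nitrogen-replete wild type had one in the pericentromeric repeats of chromosome II (1617685-1629742, -2.41). A low extract thus adds to some ratios of permanent heterochromatin on these alternative controls too.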
